A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

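The series measured messenger RNA in Saccharomyces cerevisiae strain S288C, the laboratory strain of the reference genome, grown in rich glucose medium (YPD) at 25 °C. Per the labels, tetrachloroethylene, a chlorinated solvent, was added to an exponential culture at a final 3.3 mM and cells were taken after 2 h. On each 2-colour array, Cy5-labelled cDNA came from treated cells and Cy3-labelled cDNA from cells taken before the addition. Per the labels, 3 independent biological samples were hybridised to 1 array each, and each array was scanned at high and at low laser power so that spots too bright for the scanner could be read. The 6 columns of values are therefore 2 scans of each of 3 hybridisations, and n is 3 for the tests of single genes and for every SD over hybridisations.

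The deposited values, read here as log2 ratios, were normalised by the authors by LOWESS over spots with flag 0, per the labels' descriptions. The ratio was read as Cy5 over Cy3, so a positive value stands for a higher level after treatment. Neither the base nor the direction of the ratio is stated in the labels. Both were taken from the GEO convention for 2-channel values together with the dye labels, and the highest value of 7.74 would exceed the range of a common scanner on a log10 scale. All folds and signs rest on this reading. The scanner, the spot software and the background correction are not given in the sources used here. Per the labels, the authors also merged the scans in GeneSpring, and that merged column was not used here. No spot intensities were used here, so dim spots could not be filtered, and precision is limited by the number of arrays.

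The table held 6912 features. Of these, 5513 were paired with 1 gene name by the platform annotation, 0 with several names and 1399 with none. Names were updated through a gene table of assembly R64, which matched 5508 features and left 5 under their older names. No coordinates are given, since no genome build was named for the array. The scans of a hybridisation were averaged, with a single scan used where the other had no value, and the features of a gene were averaged next. Of 5365 named genes, 99 had several features. In 68 of them all features carried identical values, and in the other 31 the median range between features was 0.264 on the log2 scale. Features of 10 genes had opposite signs, and 0 of these genes passed the threshold. ACT1 alone had 49 features. A gene needed a value in all 3 hybridisations, which 5349 genes had and 16 did not. Arrays of cDNA cannot separate near-identical gene copies, so single values of ribosomal protein pairs, TDH, HXT and AAD genes are uncertain.

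Each gene's mean log2 ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, intercept only), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. No further centring was applied. All tests were two-sided. Before the data were examined, 31 gene lists were fixed from general knowledge of yeast, among them lists of mating and of meiosis as markers of other cell states. Lists were tested with limma's camera at a preset correlation of 0.01, again with a correlation estimated from the data, and with fry, adjusted over the lists. The list of cytosolic ribosomal proteins was taken by name pattern, which also took in RPP1, a subunit of RNase P. The cell wall list held MLP1 for a kinase-like gene, a name that now stands for a protein of the nuclear pore basket. Adjusted p-values of lists are from camera with the preset correlation unless said otherwise. Errors after ± are SD over hybridisations, and list values are medians over the list's genes per hybridisation.

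Genes to be named were also set by a rule beforehand. It took the 12 highest and 12 lowest mean log2 ratios among genes past the threshold with the same sign in all 3 hybridisations. It added, for each list past the threshold, up to 4 members past the threshold with the greatest mean ratio in the list's direction, and 23 genes of interest whatever their values. These were PDR5, SNQ2, YOR1, HSP12, HSP26, HSP104, CTT1, DDR2, TPS1, GSH1, GTT1, GTT2, TRX2, OYE3, YAP1, ERG11, OLE1, INO1, MET3, RPN4, RNR3, HTA1 and CLN2. Other genes named below were chosen after their values were seen.

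The procedure was tested on simulated data made for the comparison of 3 hybridisations and 5349 genes, in 5 rounds with 200 seeded genes each. It recovered 0% of genes changed 1.5-fold, 8.36% of those changed 2-fold and 79.4% of those changed 4-fold, and 2.68% of its calls were false. These rates hold for that simulation and need not hold for the data, where 1125 genes were called. Its scan noise was smaller than the differences between the scans of hybridisation 2. A deviation shared by many genes of 1 array was not simulated. The list test found 5 of 5 lists of 30 genes shifted by 0.8 on the log2 scale and called 0 of 150 lists without a shift. Noise was drawn independently for each gene and these lists were random. The result therefore says nothing of false calls in lists whose genes move together, such as general stress genes with an estimated correlation of 0.248.

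Alternatives fixed beforehand were each scan alone, all 6 scans with the hybridisation as a random block, median centring, scaling between arrays, quantile normalisation, genes with values in at least 2 hybridisations, genes with values in all 6 scans, genes whose scans lay within 0.5 of each other, a robust variance model, a minimum fold of 1.2, and each hybridisation left out. Added after seeing the data were leaving out the low power scan of hybridisation 2, centring each block of feature IDs, taking in features without a gene name, and counting list members under every setting. Scaling used limma's median absolute value method for ratios.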

Results

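Transcript levels after 2 h in 3.3 mM tetrachloroethylene were set against those of the same yeast cultures before the addition, on 3 arrays of 2 colours each from independent biological samples. Values were log2 ratios of treated over untreated cells, with the base and direction taken from convention and dye labels since neither was stated. The high power scans held values for 6088, 5368 and 5597 of 6912 features in hybridisations 1, 2 and 3, and the low power scans for 3690, 6077 and 6145. Dyes were not exchanged and no untreated culture was sampled at 2 h, so a dye effect and the elapsed time were part of every ratio.

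The comparison asked which genes differed after exposure to the solvent. HSP12, a membrane-associated stress protein, rose most among genes past the threshold, with a mean log2 ratio of 4.24 ± 0.70 (SD, n = 3), or 18.9-fold. GPG1 (3.08 ± 0.76), the transaldolase homologue NQM1 (2.95 ± 0.57), the small heat shock protein HSP26 (2.91 ± 0.52), TMA10 (2.87 ± 0.70) and the stress gene DDR2 (2.53 ± 0.42) also rose. Among the 12 highest were VID24 (2.40 ± 0.44), which takes part in the degradation of gluconeogenic enzymes, LSC2 (2.38 ± 0.55), a subunit of succinyl-CoA ligase, GPM2 (2.37 ± 0.58), HOR7 (2.37 ± 1.2), RTC3 (2.37 ± 0.71) and the glutathione transferase ECM4 (2.21 ± 0.40). The lowest gene past the threshold was NOP7, an assembly factor of the large ribosomal subunit, with a log2 ratio of -2.27 ± 0.38 (4.81-fold lower), followed by the RNA polymerase I subunit RPA135 (-2.23 ± 0.36), RLI1 (-2.15 ± 0.42), the nucleolar methyltransferase NOP1 (-2.12 ± 0.30), RPC40 (-2.01 ± 0.51) and RPA34 (-1.98 ± 0.51). The other 6 of the 12 lowest were the adenine deaminase AAH1 (-1.97 ± 0.54), SFG1 (-1.94 ± 0.33), ALT2 (-1.93 ± 0.18), UTP23 (-1.90 ± 0.67), NMD3 (-1.86 ± 0.55) and EEB1 (-1.85 ± 0.59). Adjusted p for HSP12 was 0.00733 by limma, and each of these 24 genes had the same sign in all 3 hybridisations.

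**Figure D1:**
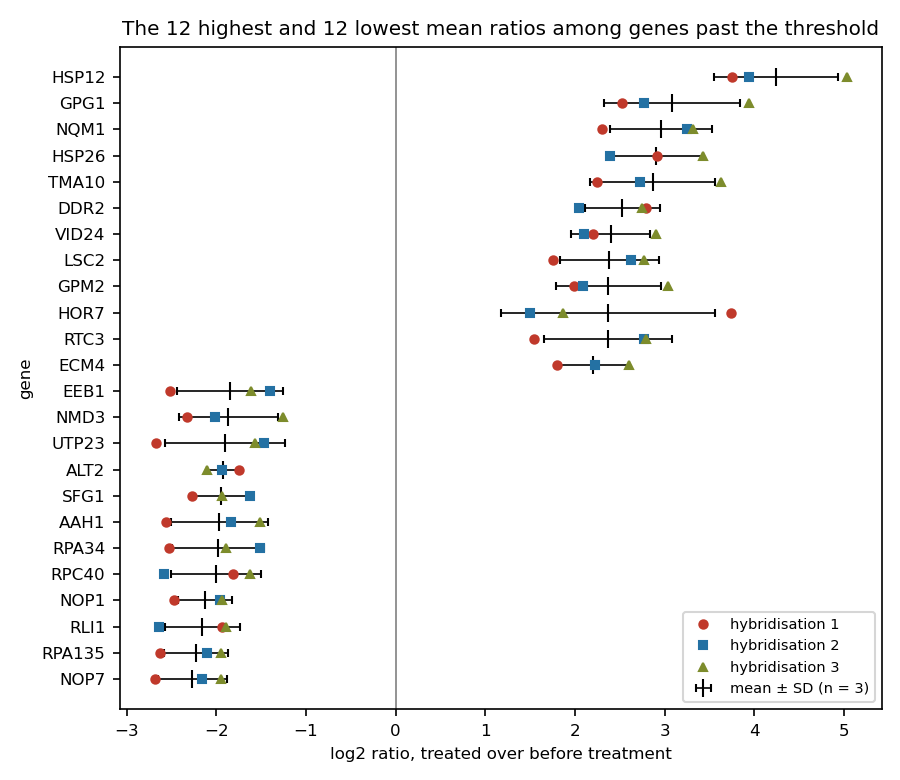
Log2 ratio of treated over untreated cells (horizontal axis) for the 12 highest and 12 lowest genes past the threshold (vertical axis), with a point for each of 3 hybridisations and a black bar for mean ± SD. HSP12 lies highest with a mean of 4.24 and NOP7 lowest with -2.27.

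In all, 1125 of 5349 genes (21.0%) passed an adjusted p of 0.05, 489 higher and 636 lower. At least 2-fold changes were found for 553 of them, 258 higher and 295 lower. At an unadjusted p under 0.05 the count was 2064. The sign was the same in all 3 hybridisations for 3147 genes (58.8%, where chance gives 25%). The count depended on single arrays: without hybridisation 1 it was 2281, with 1111 higher and 1170 lower, and without hybridisation 3 it was 1, HSP12, with 0 genes lower by limma although 743 were lower at an unadjusted p under 0.05. Every other single gene called here, and hence every list count but that of general stress, went to 0 without hybridisation 3. On the 2 arrays left, the adjusted p by limma was 0.0659 for HSP26, NOP7 and RPA135 and 0.113 for GPH1. An unadjusted p under 0.05 was kept by 1314 genes. At the level of lists, 13 passed camera without hybridisation 3, with all 12 of those called over the 3 hybridisations among them. Camera's p at the preset correlation does not measure spread over hybridisations, so this says little of their agreement. Without hybridisation 2 there were 766 genes, 393 of them lower.

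Of 29 measured targets of Msn2 and Msn4, transcription factors of the general stress response, 22 rose, 0 fell and 7 did not pass, and the list's median log2 ratio was 1.48 ± 0.41 (n = 3 hybridisations). HSP12, TMA10, DDR2 and HOR7 led the list by their means over the 3 hybridisations. The place of HOR7 rested on hybridisation 1 (3.73), and in hybridisations 2 and 3 HOR7 lay at or close to the list's median. Adjusted over the list alone, 24 rose. The catalase gene CTT1, of the same list, had a ratio of 0.03 ± 0.20. The list's adjusted p was 1.50e-13, and adjusted p = 0.460 with an estimated correlation.

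Of 20 genes of trehalose and glycogen metabolism, 6 rose and 0 fell, also when adjusted over the list alone, with a median of 0.54 ± 0.36. TSL1 (1.69 ± 0.60), a subunit of trehalose synthase, the glycogen debranching enzyme GDB1 (1.66 ± 0.65), glycogen phosphorylase GPH1 (1.29 ± 0.50) and the trehalase ATH1 (1.14 ± 0.17) were among them, so that genes of both synthesis and breakdown rose. The list's adjusted p was 0.000677, and adjusted p = 0.498 with an estimated correlation. Without hybridisation 1, 13 rose.

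Among 34 antioxidant, glutathione and thioredoxin genes, 10 rose, 1 (GPX2) fell and 23 did not pass, with a median of 0.47 ± 0.06. The glutathione transferases ECM4, GTO3 (1.93 ± 0.62) and GTT1 (1.28 ± 0.37), the mitochondrial peroxiredoxin PRX1 (1.46 ± 0.27) and thioredoxin TRX1 (1.36 ± 0.39) rose. Adjusted over the list alone, 18 rose and 3 fell. GSH1, which starts glutathione synthesis, had a ratio of -0.61 ± 0.25 and did not pass. The list's adjusted p was 0.00138, and adjusted p = 0.453 with an estimated correlation. The call ended with the high power scan alone (adjusted p = 0.0595, 22 genes measured) and with genes read in all 6 scans (0.565, 15 genes). Without hybridisation 1, 20 rose and 5 fell. After scaling between arrays, and after quantile normalisation, 18 rose and 2 fell, with hybridisation as a random block 19 rose and 3 fell, and with a minimum fold of 1.2, 7 rose and 0 fell. Of 6 aryl-alcohol dehydrogenase genes, AAD10 (0.98 ± 0.25) rose and 0 fell, with 2 higher when adjusted over the list alone. That list had a median of 0.49 ± 0.23 and an adjusted p of 0.0206, and adjusted p = 0.531 with an estimated correlation. It lost its call without hybridisation 1 (0.205), without hybridisation 2 (0.0550), with the low power scan alone (0.148) and with genes read in all 6 scans (0.109). In each of these 2 scan settings 4 of its genes were measured. AAD10 lost its own call after centring of ID blocks (adjusted p = 0.0633).

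Of 80 ribosome biogenesis genes, 77 fell, 0 rose and 3 did not pass, and 79 fell when adjusted over the list alone. The median log2 ratio was -1.16 ± 0.13, with NOP7, RPA135, NOP1 and RPA34 the lowest. The list's adjusted p was 1.13e-29, and adjusted p = 0.453 with an estimated correlation. Of 122 genes in the list of cytosolic ribosomal proteins, 36 fell, 0 rose and 86 did not pass, with 44 lower when adjusted over the list alone and a median of -0.53 ± 0.11. RPL15B (-1.63 ± 0.70), RPS0B (-1.62 ± 0.46), RPS2 (-1.62 ± 0.65) and RPL4A (-1.59 ± 0.69) were lowest, and RPP1, a subunit of RNase P rather than of the ribosome, was among the 36. The adjusted p was 2.77e-08, and adjusted p = 0.453 with an estimated correlation. Genes of this list lacked a high power value more often than the 5227 others, namely 24 of 122 against 23 in hybridisation 1, 112 against 602 in hybridisation 2 and 80 against 419 in hybridisation 3 (2-sided Fisher's exact test, adjusted p = 3.92e-28, 4.49e-88 and 4.03e-54). In hybridisation 1, 1 of the 122 lacked a low power value. With the high power scan alone, where 10 genes of the list were measured, its adjusted p was 0.204, and it was 0.530 over the 9 genes read in all 6 scans and 0.217 without the low power scan of hybridisation 2. Without hybridisation 1, 80 fell, after centring of ID blocks 22 did, and with a minimum fold of 1.2, 17 did.

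Of 68 genes of mitochondrial ribosomal proteins, 13 rose, 55 did not pass and 0 fell, 15 when adjusted over the list alone, with a median of 0.41 ± 0.21. MRP10 (1.86 ± 1.28), MRPL33 (1.29 ± 0.27), MRP2 (1.09 ± 0.27) and MRPL23 (1.09 ± 0.23) were highest, MRP10 had 1.12 without hybridisation 1, below MRPL23 (1.21) and MRPL33 (1.19), and its call ended with a minimum fold of 1.2 (adjusted p = 0.0526). The list's adjusted p was 1.37e-06, and adjusted p = 0.531 with an estimated correlation. Without hybridisation 1, 41 rose, without hybridisation 2, 5 did, with hybridisation as a random block 25 did, and with a minimum fold of 1.2, 3 did. Of 22 genes of the tricarboxylic acid and glyoxylate cycles, LSC2, the isocitrate dehydrogenase subunit IDH1 (1.63 ± 0.36) and the gluconeogenic enzyme PCK1 (1.56 ± 0.40) rose and 0 fell, with the same 3 to 0 split when adjusted over the list alone. The list's median was 0.33 ± 0.27 and its adjusted p 0.00231, and adjusted p = 0.531 with an estimated correlation. Its call ended with the high power scan alone (adjusted p = 0.126), with the low power scan alone (0.0580) and without the low power scan of hybridisation 2 (0.134). It also ended with genes read in all 6 scans (0.861), where 7 of the 22 were left and their mean turned to -0.04. Without hybridisation 1, 13 rose, after scaling between arrays and with hybridisation as a random block 6 did, and with the high power scan alone 1 of 14 measured genes did.

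Genes of ubiquitin, vacuolar proteolysis and autophagy were represented by 21 genes, of which 7 rose and 0 fell, with a median of 0.45 ± 0.19. They included ATG8 (1.82 ± 0.49), the ubiquitin-like protein of autophagosomes, the selective autophagy receptor ATG19 (1.51 ± 0.14) and the ubiquitin-conjugating enzymes UBC8 (1.497 ± 0.25) and UBC5 (1.2 ± 0.19). Adjusted over the list alone, 10 rose and 2 fell, and with a minimum fold of 1.2, 4 rose. The list's adjusted p was 0.00444, and adjusted p = 0.453 with an estimated correlation. Of 24 genes of iron and copper uptake, 10 rose and 1, the reductase FRE1, fell, also when adjusted over the list alone, with a median of 0.69 ± 0.41. The haem oxygenase HMX1 (2.20 ± 0.05), the cell wall mannoproteins FIT1 (1.81 ± 0.69) and FIT3 (1.77 ± 0.86) and the copper transporter CCC2 (1.42 ± 0.24) were highest. The list also held the metallothionein CRS5 and the messenger RNA-binding protein TIS11, which are not transporters and rose. The adjusted p was 6.25e-05, and adjusted p = 0.498 with an estimated correlation. The call ended with genes read in all 6 scans (adjusted p = 0.0978, 6 of 24 genes left), and without hybridisation 1, 16 rose.

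Of 54 genes of amino acid synthesis, 19 fell and 0 rose, with a median of -0.50 ± 0.10. Adjusted over the list alone, 23 fell and 2 rose. LYS4 (-1.77 ± 0.10) of lysine synthesis, ARG1 (-1.40 ± 0.18) of arginine synthesis, the asparagine synthetase ASN2 (-1.30 ± 0.27) and the branched-chain transaminase BAT1 (-1.18 ± 0.11) were lowest. The adjusted p was 6.25e-05, and adjusted p = 0.453 with an estimated correlation. Without hybridisation 1, 32 fell and 6 rose, and without hybridisation 2, 7 fell and 1 rose. After centring of ID blocks 11 fell and 1 rose, and with a minimum fold of 1.2, 6 fell and 0 rose. Among 28 cyclins and cell cycle markers, 5 fell and 0 rose, 8 when adjusted over the list alone, with a median of -0.45 ± 0.18. These were the mitotic cyclins CLB2 (-1.54 ± 0.57), CLB1 (-1.37 ± 0.71) and CLB4 (-1.11 ± 0.64), the cyclin-dependent kinase inhibitor FAR1 (-1.10 ± 0.08) and the polo kinase CDC5 (-0.86 ± 0.46). The adjusted p was 0.00587, and adjusted p = 0.498 with an estimated correlation. The list's call ended with the low power scan alone (adjusted p = 0.455, 12 genes measured), with genes read in all 6 scans (0.437, 10 genes) and with scans within 0.5 (0.472, 13 genes). Without hybridisation 1, 10 fell. After scaling and after quantile normalisation 8 fell, with hybridisation as a random block 10 did, and with a minimum fold of 1.2, 3 did. The call for CLB1 ended with the high power scan alone (0.0654) and without the low power scan of hybridisation 2 (0.0597), and that for CLB4 with a minimum fold of 1.2 (0.0677) and after centring of ID blocks (0.0757).

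**Figure D2:**
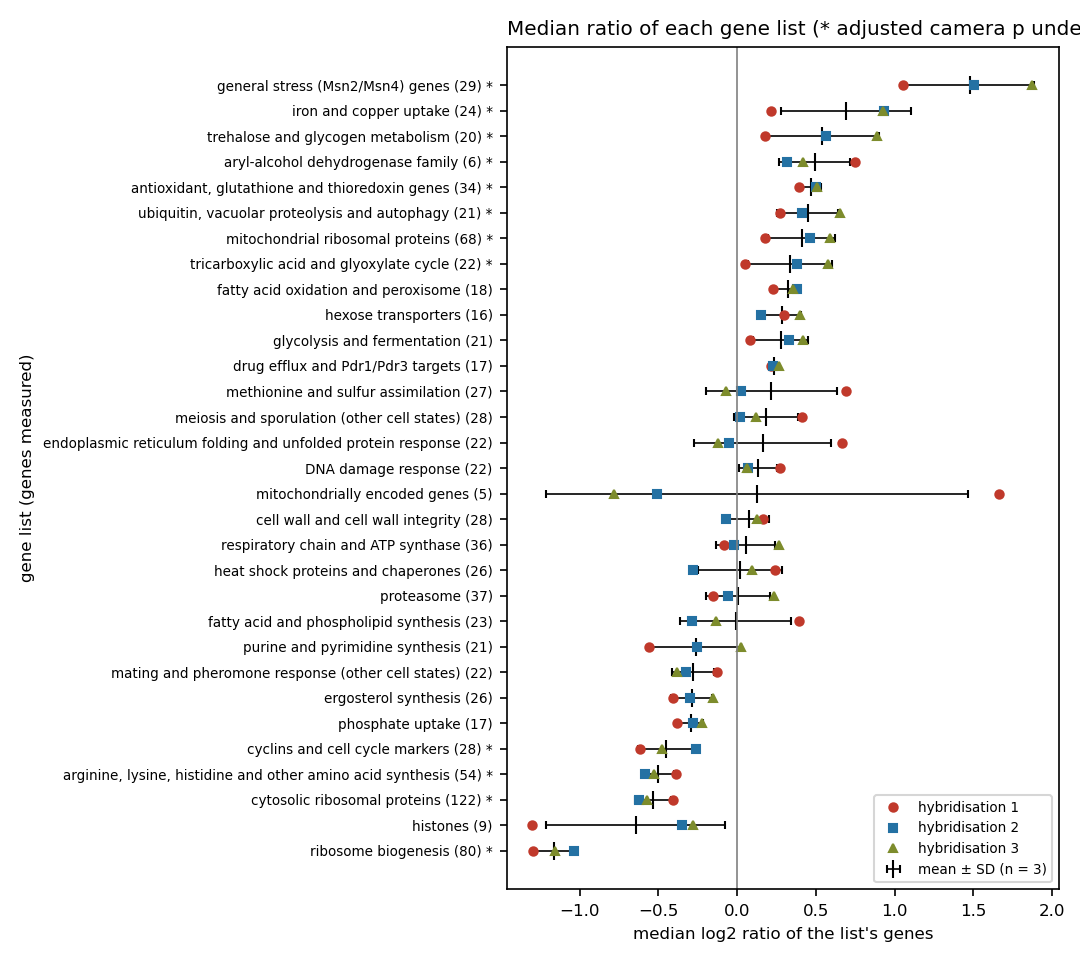
Median log2 ratio of the genes of each of 31 lists (horizontal axis) per hybridisation, with a black bar for mean ± SD; the number of genes measured stands in parentheses, and an asterisk marks an adjusted camera p under 0.05 at the preset correlation. General stress genes lie highest at 1.48 and ribosome biogenesis genes lowest at -1.16.

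In total 12 of 31 lists passed camera at the preset correlation, 8 higher and 4 lower, and 16 did at an unadjusted p under 0.05. With an estimated correlation 0 lists passed camera, with a lowest adjusted p of 0.453 and 2 lists at an unadjusted p under 0.05. That setting also rests on 2 residual degrees of freedom. For antioxidant genes the estimated correlation was 0.0083, below the preset 0.01, and the unadjusted camera p still went from 0.000355 to 0.0676. For that list the loss of the call therefore cannot be put down to correlation between genes alone. Other called lists had estimated correlations far above the preset, such as 0.678 for aryl-alcohol dehydrogenases, 0.354 for the tricarboxylic acid list and 0.248 for general stress genes. Values near or below the preset were found too, such as 0.0148 for cytosolic ribosomal proteins and -0.0077 for the ubiquitin list. By fry, which asks whether a list's genes moved on balance in 1 direction, 4 lists passed, those of antioxidant genes (adjusted p = 0.0395), ribosome biogenesis, amino acid synthesis and the DNA damage response (0.0386 each), general stress genes were at 0.0506, and 29 passed its test of change in either direction.

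The remaining 19 lists did not pass camera. Among 17 drug efflux genes and Pdr1 or Pdr3 targets, 5 rose and 0 fell (adjusted p = 0.118), namely AQR1 (2.06 ± 0.52), ICT1, RSB1, the transporter PDR5 (1.37 ± 0.99) and PDR16. Adjusted over the list alone, 7 rose and 1 fell. That list passed without hybridisation 1 (adjusted p = 0.00499) and without hybridisation 2 (0.0429), and PDR5 lost its call with scans within 0.5 (0.0506) and with a minimum fold of 1.2 (0.0757). With scans within 0.5, 1 of 10 measured genes of that list rose. Of 26 heat shock proteins and chaperones, HSP26, SSE2 (1.43 ± 0.26) and HSP10 (0.82 ± 0.19) rose, BTN2 (-1.32 ± 0.52) and CUR1 (-0.67 ± 0.18) fell and 21 did not pass (adjusted p = 0.624). Without hybridisation 1, 7 of these rose and 4 fell, and after centring of ID blocks 5 rose and 0 fell by limma. The mean over that list was 0.14 and the median of its gene means -0.09. Of 21 glycolytic and fermentation genes, TDH1, TDH2, TDH3, GPM1 and TPI1 rose and 0 fell (adjusted p = 0.0646), and the list passed without hybridisation 1 (0.00887), with scans within 0.5 (0.0425) and after centring of ID blocks (0.00690). Without hybridisation 1, 8 rose and 1 fell, and without hybridisation 2, 3 rose. Of 16 hexose transporter genes, HXT16 and MTH1, a regulator of glucose-responsive transcription rather than a transporter, rose (adjusted p = 0.0621), and 0 did when adjusted over the list alone by limma. The list passed with the high power scan alone (0.0126), with scans within 0.5 (0.0360) and without the low power scan of hybridisation 2 (0.0176), and 5 rose without hybridisation 1 and 1 without hybridisation 2. Of 18 genes of fatty acid oxidation, CAT2 and PEX21 rose (adjusted p = 0.0634), 10 rose and 2 fell without hybridisation 1, and 0 rose or fell by limma without hybridisation 2.

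Of 9 histone genes, HHF2 (-1.0 ± 0.45), HHT2 and HTB2 fell (adjusted p = 0.0634), and the list passed without hybridisation 2 (0.0289) and without hybridisation 3 (0.0277). Without hybridisation 1, 1 rose and 3 fell, and after centring of ID blocks 0 fell by limma. Of 17 phosphate uptake genes, PHO3 (-1.52 ± 0.27), PHO84, PHO5 and PHO11 fell (adjusted p = 0.118), and the list passed with the low power scan alone (0.0202). Of 26 ergosterol genes, ERG7, ERG3, UPC2 and NCP1 fell and ERG28 rose (adjusted p = 0.121). Without hybridisation 1, 10 fell and 5 rose, after scaling 8 fell and 1 rose, after quantile normalisation 7 fell and 1 rose, and after centring of ID blocks 0 fell by limma and 1 rose. Of 21 genes of purine and pyrimidine synthesis, 4 fell and 2 rose (adjusted p = 0.124). In fatty acid and phospholipid synthesis, OPI3 (2.03 ± 0.86) and CKI1 rose and ELO3, ELO2 and FAS2 fell among 23 genes (adjusted p = 0.870), with a mean over the list of 0.08, a median of -0.01 and a test pointing down, and without hybridisation 1, 4 rose and 5 fell and the mean was -0.07. Methionine and sulfur genes had 2 higher and 3 lower of 27 (adjusted p = 0.340), 4 and 7 without hybridisation 1, and 4 and 1 without hybridisation 2. The cell wall list had 1 higher and 4 lower of 28 (adjusted p = 0.679), with MLP1 of the nuclear pore among the 4, and 4 higher and 7 lower without hybridisation 1 and 0 and 1 without hybridisation 2. The respiratory chain had 3 higher and 1 lower of 36 (adjusted p = 0.292), the DNA damage response 3 and 1 of 22 (0.293), and endoplasmic reticulum folding 1 and 1 of 22 (0.392), with 0 higher when adjusted over the list alone. Without hybridisation 1 these lists had 8 and 5, 5 and 3, and 2 and 5 genes higher and lower, and without hybridisation 2 the respiratory chain had 4 and 0 and the DNA damage response 3 and 2. The proteasome list had RPN14 higher and RPN2 lower of 37 (adjusted p = 0.274), with 0 and 0 when adjusted over the list alone by limma and without hybridisation 2, and 8 higher and 3 lower without hybridisation 1.

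For other cell states, the mating list had 1 gene higher and 6 lower of 22 (adjusted p = 0.158), the latter including STE3 (-1.57 ± 0.36) and MF(ALPHA)2 (-1.42 ± 0.61), and passed without hybridisation 1 (0.00499), where 2 rose and 11 fell, against 2 and 4 without hybridisation 2. The meiosis list had 2 higher and 1 lower of 28 (adjusted p = 0.118) and passed without hybridisation 2 (0.0188) and after centring of ID blocks (0.0494), with 6 higher and 2 lower without hybridisation 1 and 5 and 1 without hybridisation 2. With the low power scan alone 1 of the 28 had a value in all 3 hybridisations, so the others rested on the high power scan in at least 1 array. Of 5 mitochondrially encoded genes, 0 passed by limma (adjusted p of the list 0.544), with medians of 1.66, -0.51 and -0.78 in hybridisations 1, 2 and 3, a mean over the list of 0.44 and a median of -0.05. In this list 0 genes had low power values in all 3 hybridisations, and OLI1 (4.13), ATP8 (3.41), COX3 (1.66) and COX2 (1.48) had none in hybridisation 1. Without hybridisation 1, 4 of the 5 fell, 1 rose and the mean was -0.55, without hybridisation 2, 2 rose and 0 fell, and after scaling 1 rose. With a minimum fold of 1.2, 0 genes passed by limma in the methionine, hexose transporter, histone and proteasome lists, and 2 rose in drug efflux, 2 rose and 1 fell among chaperones, 1 rose in fatty acid oxidation, 1 fell in ergosterol synthesis, 1 rose and 1 fell in fatty acid and phospholipid synthesis and 2 fell in the cell wall list. With hybridisation as a random block, 5 rose in each of the methionine, cell wall, chaperone and respiratory chain lists, 4 in each of the hexose transporter, fatty acid oxidation and endoplasmic reticulum folding lists and 6 in meiosis, and 8 fell in ergosterol synthesis. For the 19 lists that did not pass, counts adjusted over the list alone equalled those given, apart from the differences stated and from mating, with 2 higher and 7 lower.

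Of the 23 genes fixed for reporting, 5 rose (PDR5, HSP12, HSP26, DDR2 and GTT1), 0 fell and 18 did not pass. INO1, which starts inositol synthesis, had ratios of 7.74, 1.32 and 0.86 in hybridisations 1, 2 and 3 and an adjusted p of 0.0946, the first of these from the high power scan alone. The fatty acid desaturase OLE1 (-0.95 ± 1.11), the cyclin CLN2 (-1.04 ± 1.21) and the reductase OYE3 (1.26 ± 1.27) also varied more between hybridisations than their means. Values close to the threshold were those of the transporter SNQ2 (-0.74 ± 0.39, adjusted p = 0.0516), TRX2 (0.72 ± 0.38), YAP1 (0.71 ± 0.44) and GSH1. HSP104 (0.54 ± 0.25), TPS1 (0.40 ± 0.29), GTT2 (0.59 ± 0.73), MET3 (0.37 ± 0.12), RPN4 (0.50 ± 0.73) and RNR3 (-0.57 ± 0.81) did not pass. CTT1, YOR1 (0.06 ± 0.30), ERG11 (-0.06 ± 0.23) and the histone gene HTA1 (-0.12 ± 0.52) lay within 1 SD of 0, and the sign of each turned with a hybridisation left out. Without hybridisation 1, SNQ2, HSP104, TPS1, GSH1, GTT2, TRX2, OYE3, YAP1, INO1 and RNR3 passed, INO1 with a ratio of 1.09, and without hybridisation 2, OYE3, OLE1, INO1 and CLN2 passed. With hybridisation as a random block, SNQ2, HSP104, GSH1, TRX2, OYE3, YAP1, OLE1, INO1 and CLN2 passed. That setting used 1 correlation for all genes and counted the 2 scans of an array in part as separate observations. OLE1, CLN2 and OYE3 thus passed there although their SD over 3 hybridisations exceeded their mean. After scaling and after quantile normalisation SNQ2, GSH1, TRX2, OYE3, YAP1 and INO1 passed, and with the low power scan alone the first 5 of these and OLE1 did. After centring of ID blocks SNQ2, HSP104 and TPS1 passed, and after centring on the median TRX2 did. PDR5 lost its call with scans within 0.5 and with a minimum fold of 1.2.

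Hybridisation 1 differed from the others. Across 5349 genes, which are not independent replicates, r was 0.836 between hybridisations 2 and 3, 0.562 between 1 and 2 and 0.556 between 1 and 3 (Spearman's rho 0.797, 0.577 and 0.562). The SD over genes was 0.899 in hybridisation 1, 0.649 in hybridisation 2 and 0.669 in hybridisation 3. Between the scans of 1 array, r was 0.951, 0.778 and 0.892 in hybridisations 1, 2 and 3, and the scans differed by over 0.5 for 9.26%, 30.1% and 9.87% of features.

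**Figure D3:**
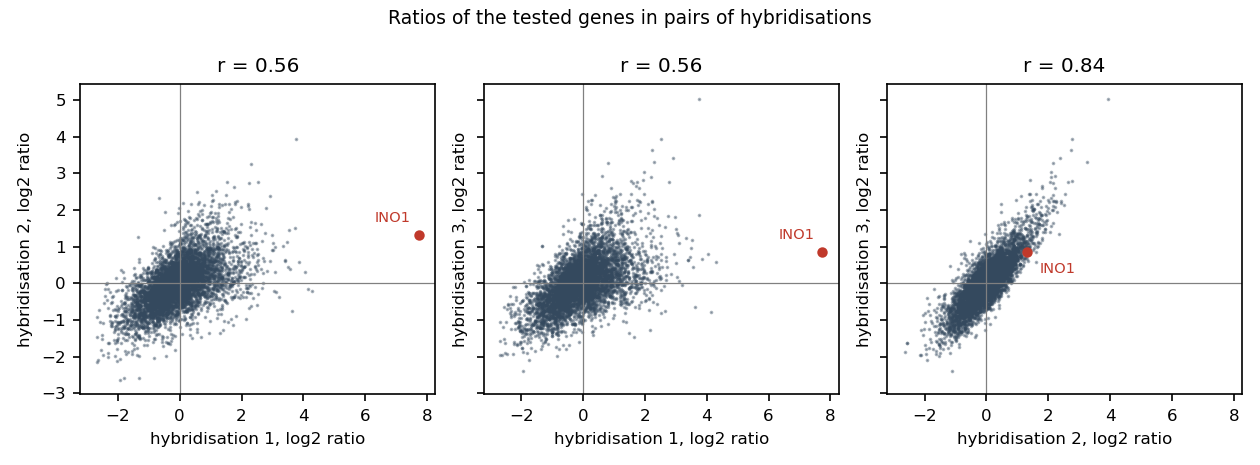
Log2 ratios of 5349 genes in each pair of hybridisations (both axes log2 ratio), with INO1 in red. Points lie closer to a line for hybridisations 2 and 3 (r = 0.836) than for the pairs with hybridisation 1 (0.562 and 0.556).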

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

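Features without a gene name were left out of the comparison, and some of them carried a signal of their own, which is why they are given here. Of 1399 such features, 649 had a value and 641 could be tested, and 27 of them passed the adjusted threshold by limma, 12 higher and 15 lower. The greatest change was that of feature 8010504, singled out after its value was seen, with ratios of 2.67, 3.40 and 3.43 in hybridisations 1, 2 and 3 and an adjusted p of 0.00166. The genes behind these features were not identified here, and no explanation was tested.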

How the results depend on the processing

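Leaving out the low power scan of hybridisation 2, taking in features without a name and centring ID blocks were chosen after seeing the data. Gene counts moved by over 1.5 times under the settings given next. Genes read in all 6 scans gave 546 changed, 289 higher, 257 lower, 204 at least 2-fold and 6 lists, over 2672 genes tested. Scans within 0.5 gave 691, 272, 419 and 335 genes, over 3435 tested. A minimum fold of 1.2 gave 514 changed, 230 higher and 284 lower, and the random block 1741 changed and 803 higher. Scans of 1 array counted in part as separate observations in the random block, so its larger counts do not rest on more cultures. The 2-fold count was 348 with the high power scan alone and 364 without the low power scan of hybridisation 2, and the low power scan alone gave 417 genes lower. With a hybridisation left out, genes changed ranged from 1 to 2281, higher from 1 to 1111, lower from 0 to 1170 and at least 2-fold from 1 to 739. Fewer genes were tested in the scan settings, and the cause of the other shifts was not tested. Other gene counts stayed within 1.5 times the reported ones. A similar count did not always mean the same genes. After centring of ID blocks 898 genes passed, 697 of them among the 1125 reported. Without hybridisation 2, 624 of the 766 were among them. Scaling and quantile normalisation kept all 1125.

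Some signs turned, and the cause was not tested except where only the set of genes changed. With a hybridisation left out, YOR1 ranged from -0.0288 to 0.232, CTT1 from -0.0264 to 0.144, ERG11 from -0.195 to 0.0128 and HTA1 from -0.305 to 0.172. List means ranged from -0.120 to 0.307 for methionine, -0.0729 to 0.177 for fatty acid and phospholipid synthesis, -0.0188 to 0.0217 for the cell wall, -0.0896 to 0.427 for endoplasmic reticulum folding and -0.548 to 1.02 for mitochondrially encoded genes. Fatty acid and phospholipid synthesis was -0.0797 with the low power scan alone. The cell wall list was -0.000111 after scaling, -0.00386 after quantile normalisation and -0.0625 with scans within 0.5, where 17 of 28 genes were left. With genes read in all 6 scans, the tricarboxylic acid list, reported at 0.526, was -0.0376 over 7 of 22 genes. The purine list (-0.244) was 0.0288 over 11 of 21 genes and the mating list (-0.245) 0.196 over 5 of 22. Gene values were unchanged with genes read in all 6 scans and with scans within 0.5, so turns there came from the genes left out. The purine list was 0.0201 with the high power scan alone and 0.0267 without the low power scan of hybridisation 2, each over 11 genes. Of 1172 values of named genes under the alternatives, 1054 kept direction and side of the threshold, 67 lost the call, 45 gained it and 6 changed sign. Of 426 values of lists, 381 kept both, 16 lost the call, 14 gained it and 15 changed sign. A value that changed sign was counted only as such, also where its call was lost, as for the tricarboxylic acid list with genes read in all 6 scans. Camera was not run with the random block, a minimum fold or unnamed features. Signal over background was not used here, so its limit on dim genes is unknown.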

Other observations

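The 6 lists of this part, and the tests of the scans of hybridisation 1 and of its lists, of the low power scan of hybridisation 2, of Ino2 and Ino4 targets, of glucose exhaustion and of elapsed time, were chosen after the results were seen. Of 19 genes for subunits of RNA polymerases I and III, which transcribe ribosomal and transfer RNA, 13 fell, 0 rose and 6 did not pass, with a median log2 ratio of -1.08 ± 0.03 (n = 3 hybridisations), and 6 of the 19 were also in the ribosome biogenesis list. They included the polymerase III subunits RPC31 (-1.31 ± 0.19) and RET1 (-1.29 ± 0.21). The adjusted p over the 6 lists was 1.82e-07 by limma's camera, and adjusted p = 0.1502 with an estimated correlation. Of 19 cytosolic aminoacyl-tRNA synthetases, which charge transfer RNA with amino acids, 10 fell and 0 rose, with THS1 (-1.40 ± 0.34) and CDC60 (-1.32 ± 0.68) lowest and a median of -0.83 ± 0.33 (adjusted p = 2.34e-05, and adjusted p = 0.249 with an estimated correlation). Of 35 translation factors, 9 fell and 0 rose, with a median of -0.44 ± 0.10 (adjusted p = 0.000421, and adjusted p = 0.1502 with an estimated correlation). The galactose list had 1 gene higher (GAL7, 2.06 ± 1.29, and 1.32 without hybridisation 1) and 0 lower of 7 (adjusted p = 0.0917).

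Hybridisation 1 stood apart from hybridisations 2 and 3, and its deviation from their mean was greatest for INO1 (6.66) and the mitochondrial gene OLI1 (4.60). What hybridisations 2 and 3 did not predict recurred in both scans of the array (partial r = 0.930 across the 3640 features read by both, INO1 and OLI1 not among them), which argues against scan noise for those features. Feature ID blocks held 10.0% of the variance of the deviation against 3.09% in permuted data. That argues against place on the array as the whole cause, as far as the ID encodes it, and leaves a part open. Noise of single spots as the whole cause is argued against by 15 of 31 lists whose median deviation lay outside the central 95% of random lists, where 1000 sets with random signs gave at most 12, and its part stays open, since different features of a gene gave r = 0.657 with a 95% bootstrap interval from 0.191 to 0.821 over 31 genes, a set restricted to genes whose features differ after identical copies were found. For INO1 and OPI3 a candidate explanation is a culture in another state of the Ino2 and Ino4 regulon, a hypothesis first set against the whole deviation and narrowed to these genes after its result. A state shared by the cells before and after treatment would cancel in the ratio, so only one that differed between them could apply. The 13 other targets, 10 of them also in lists fixed beforehand, deviated upwards by a median of 0.78, at percentile 99.98 of random lists. The list of fatty acid and phospholipid synthesis, which shares genes with these targets, lay at percentile 99.97. Lists of methionine, cytosolic ribosomal proteins, endoplasmic reticulum folding and mitochondrially encoded genes reached percentile 100 as well, so the shift was not particular to these targets, and a difference between cultures was not separated from one between arrays.

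The scans of hybridisation 2 differed from each other more than those of the other arrays. Over the same features, its low power scan correlated with hybridisation 3 at r = 0.689 and its high power scan at 0.885, a difference of 0.196, which is consistent with noise in the low power scan. ID blocks held 38.7% of the variance of the scan difference against 3.62% in permuted data, too little for the whole and too much to exclude a part, and centring them left r between the scans at 0.782, from 0.778. In hybridisations 1 and 3 they held 13.1% and 22.7% of it, against 5.18% and 3.43% in permuted data. No biological explanation applies to scans of 1 array. Without that scan 945 genes passed, 818 of them shared with the 1125.

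Of 80 ribosome biogenesis genes 77 fell, and of 29 general stress genes 22 rose, a pattern that could come from the solvent, from glucose running out or from time alone. Exhaustion of glucose as the whole source is weakly argued against by 18 genes repressed by glucose, 9 of them also in lists fixed beforehand. Their median ratio was 0.464 (SD 0.170) against 1.48 for general stress genes, and it was 0.656, 0.402 and 0.335 in hybridisations 1, 2 and 3. The bound for this reading was set after the values were seen, and dim spots of the glucose-repressed list could not be filtered. In that list PCK1, CAT2, JEN1 and SIP4 rose and ATO3 fell, ADH2 was at -0.50 ± 0.72 and SUC2 at -0.06 ± 0.61 (-0.09 and -0.41 without hybridisation 1, and SUC2 at 0.12 without either other), and its adjusted p was 0.00221, and adjusted p = 0.1502 with an estimated correlation, so a partial fall in glucose stays open. The solvent and the elapsed time cannot be told apart, since 0 untreated cultures taken at 2 h were among the samples.

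For the number of genes past the threshold, 1 of 4 assignments of signs to the 3 arrays, the real one, gave as many as 1125, and the highest of the others gave 0. These assignments are too few for a share under 0.05.

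The list of Ino2 and Ino4 targets had CKI1 higher and FAS2 lower of 13 genes, with medians of 0.43, -0.44 and -0.13 in hybridisations 1, 2 and 3 (adjusted p = 0.943, and adjusted p = 0.982 with an estimated correlation).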
